A study of Mus musculus with 4 samples.

How the data were processed

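Capture Hi-C libraries were made from distal limb buds of WT, DelB, DelBs and InvF embryos at E11.5, with 1 library per genotype. Per the labels' protocols, cells were dissociated and fixed with formaldehyde, and adaptor-ligated DNA was enriched with custom SureSelect probes and sequenced in paired-end mode. Per the submitters' processing notes, reads were mapped with Bowtie2 2.2.6 and the build was mm9. The deposited raw maps hold whole-number counts of read pairs per pair of 10 kb bins, at a mapping quality of 30 per the file names. The deposited normalized maps hold a signal per pair of bins, made by the authors with KR matrix balancing per the file names. KR balancing brings every bin of a library to about the same sum, and the balanced totals were 99.6% to 99.8% of the raw totals. The deposited difference maps hold a score per pair of bins. How it was made is not given in the sources used here. It was recovered from the values: (mutant counts brought to the WT sum over the pairs within the difference map, without deleted bins, minus WT counts) divided by the mean WT count at that distance, set to 0 for most pairs. Over 99.9% of the values that were not 0, outside the first row and last column, lay within 5% of this. Whether PCR duplicates were removed is not given in the sources used here, so intervals treat counts as independent and cover counting error alone. No column of the files was left without a sample (0 unmatched).

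Everything else was computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. A deletion was the longest run of bins under 10% of the WT share of counts, passing over bins under 10% of the WT median. An inversion was the pair of breakpoints at least 200 kb apart with the highest score, which is the mean log2 ratio over the 100 kb corner blocks that an inversion joins minus that over the corner blocks it does not bring closer. Libraries were scaled to the sum of counts over pairs of bins 20 kb to 2 Mb apart that lie on the same side of, and outside, every rearranged interval; this gave factors of 1.43 for DelB, 1.50 for DelBs and 1.24 for InvF relative to WT. By the total of all counts the factors would be 1.08, 1.13 and 1.18. Ratios have exact conditional binomial intervals and observed over expected values have exact Poisson intervals, at the 95% level. The expected level is the mean count of the same library at that distance over same-side pairs, at the distance on the rearranged allele. It does not correct for uneven coverage of bins. Residual shares in the deletions leave out the last bin, which may hold the break.

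Insulation was the log2 of the mean count in a 200 kb window, over pairs at least 20 kb apart, relative to the library mean, with deleted bins removed and inverted bins turned. Boundaries were minima at least 0.2 below the highest value within 200 kb on each side, and 2 boundaries matched within 50 kb. Blocks of 100 kb were compared where at least 1 of the libraries had 50 counts, with a pseudocount of 1. Named regions were fixed by rule before the data were examined: the rearranged intervals, their 100 kb, 250 kb and 500 kb flanks, the WT boundaries, and the 10 highest and 10 lowest 100 kb blocks per mutant, merged where they touch. The windows of 100 kb named along a profile, the 40 kb parts at the right junction and the first DelB boundary beyond its deletion were chosen after the values were seen. Genes were taken from the GRCm38 RefSeq table for names and neighbours alone.

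The functions were tested on simulated data drawn from the WT decay and coverage. A simulated deletion of 120 bins and a simulated inversion of 120 bins were located with 0 bins of error, and a map without either gave 0 deleted bins and a highest inversion score of 0.46 on the log2 scale. All 200 blocks changed by 0.25, 0.4, 2.5 or 4 fold passed 1 log2 unit (100% of the 50 at each fold) with 1 of 3998 unchanged blocks, and 15 of 15 simulated boundaries were found. All simulated boundaries had the same strong drop in contacts, so the finding of shallow ones near the limit of 0.2 was not tested. The ratio across the simulated deletion was 5.58 against a true 5.55. Observed over expected was 1.09 there, although the simulation held no excess. This came from the simulated deletion of 120 bins alone, with 500 kb flanks at another position. The error of this measure at the real flanks is therefore not known.

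There were 3 departures made after values had been seen. The spread of insulation was first taken over 18 boundaries over 200 kb from every breakpoint, and then over the 15 that also lie outside the rearranged intervals; the SD over 18 was 0.05 in DelB, 0.11 in DelBs and 0.13 in InvF. For blocks with each distance matched, the expected level was first held at its last value beyond its range of 3.78 Mb, and such blocks were then left out; both versions are given with the alternatives. The test of reads carried over from InvF was kept as first written, and a version with each distance matched was added beside it.

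Alternatives fixed before the data were examined used the balanced values, other scalings, flanks, windows, block sizes and count limits, and left out poorly covered bins (21 bins) or bins at breakpoints (20 bins).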

Results

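Chromatin contacts were measured by capture Hi-C in distal limb buds of mouse embryos at E11.5. Capture Hi-C counts how often pairs of genome segments are ligated after crosslinking, and here probes enriched the region around Epha4, which encodes an ephrin receptor tyrosine kinase. There were 4 genotypes with 1 library each: wild type (WT) and 3 homozygous mutants named DelB, DelBs and InvF. The maps covered chromosome 1 from 71000001 to 81000000 in build mm9, as 1000 bins of 10 kb, which makes 500500 pairs of bins. The libraries held 5155274 counts in WT, 5543587 in DelB, 5832748 in DelBs and 6073471 in InvF, and 55.4% to 67.0% of the pairs had a count. With 1 library per genotype no spread between embryos could be measured and no p-value is given. All 95% intervals are exact and cover counting error alone. Ratios across the deletions and at the InvF junctions and breakpoints were set beside blocks of the same size and separation that no rearrangement touched. The DelB to DelBs ratio of observed over expected was set beside such blocks 200 kb apart. That is the separation on the DelBs allele, while the flanks adjoin on the DelB allele. Other ratios have counting intervals alone.

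The intervals removed or turned in the mutants were located from the maps themselves. DelB lacked 1670 kb, from 76390001 to 78060000. DelBs lacked 1470 kb of the same stretch, from 76390001 to 77860000, so that both deletions shared their upstream end and a 200 kb segment next to the downstream end was missing from DelB alone. InvF lacked no run of bins, and its new junctions placed a 1070 kb inversion from 74830001 to 75900000. The inversion score was 3.89 on the log2 scale at these breakpoints and at most 0.44 elsewhere in InvF, against highest scores of 0.78 in DelB and 0.73 in DelBs. Inside the deleted interval the counts stood at 2.23% of the WT level in DelB (2.204% to 2.26%) and at 1.14% in DelBs (1.12% to 1.16%). From the published description of the mutants, both deletions remove Epha4 and the inversion lies near Wnt6, a gene for a secreted signalling protein, while Pax3, a transcription factor gene, lies beyond the deletions. These gene positions were not checked here, because no mm9 annotation was used. In the RefSeq gene table of the GRCm38 assembly, Slc4a3, Epha4 and Pax3 are neighbours with 0 other protein-coding genes between them, and 31 protein-coding genes lie between Wnt6 and Slc4a3.

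The deletions ask what becomes of contacts between the flanks when the domain between them is removed. In DelB the 500 kb upstream of the deletion, from 75890001 to 76390000, contacted the 500 kb downstream of it 8.62 times as often as in WT (8.44 to 8.80, from 113007 and 9149 counts). In DelBs the corresponding flanks met 3.70 times as often as in WT (3.63 to 3.76, from 82440 and 14896 counts). In InvF this stretch keeps its order except for the first 10 kb of the upstream flank, which lie in the inverted interval. There the ratio of InvF to WT was 1.05 for the same blocks in both cases. Seen along the chromosome, the upstream flank of DelB had 11.2 times its WT contacts with the window from 78100001 to 78200000 and 8.21 times with the window from 78400001 to 78500000, falling to 2.02 times at 79000001 to 79100000. The flank of DelBs had 3.83 times its WT contacts at 77900001 to 78000000 and 4.03 times at 78400001 to 78500000.

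Over 145 placements of untouched blocks of the same size and separation the DelB to WT ratio lay between 0.89 and 1.18, and over 185 placements the DelBs to WT ratio lay between 1.02 and 1.23. Neither observed ratio was reached by any placement. Such placements, here and below, were moved 10 kb at a time and share most of their counts, so they are not independent. A shorter distance between the flanks raises contacts by itself, so the counts were also set against the decay with distance of the same library at the distance left on the allele. Observed over expected was 1.60 in DelB (1.59 to 1.61) and 1.12 in DelBs (1.11 to 1.12). In WT, at its full distance, the same blocks stood at 1.98 and 2.57 times the expected level, so the flanks already met more often than the decay gives before any deletion. Neither value is settled as an excess. A simulated deletion with no excess gave 1.09, with 500 kb flanks at another position, and smaller flanks were not simulated. The values also moved with the setting. With 250 kb flanks they were 1.11 in DelB and 0.935 in DelBs. With 100 kb flanks they were 1.02 (0.999 to 1.04) and 0.958 (0.940 to 0.976). With balanced values they were 1.198 and 0.823, although balancing also raised the deleted bins.

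**Figure D1:**
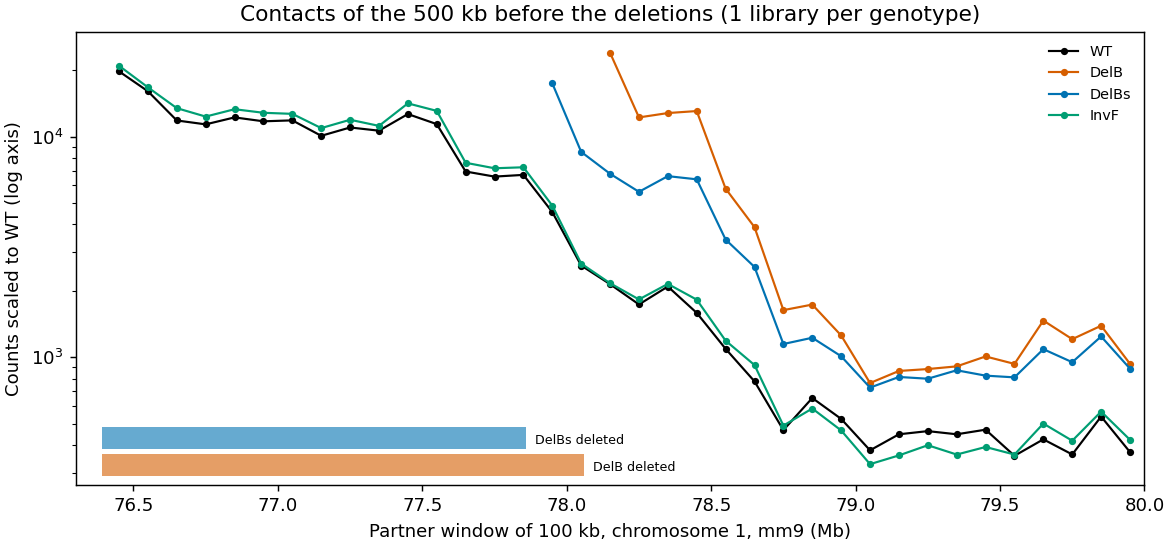
Contacts of the 500 kb before the deletions with windows of 100 kb, as counts scaled to WT on a log axis against the position in Mb, with 1 line per library and no error bars. Windows that overlap a deletion are left out for that library. At 78100001 to 78200000 the counts were 11.2 times WT in DelB and 3.16 times in DelBs.

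DelB and DelBs differ by the 200 kb segment from 77860001 to 78060000, so their comparison asks what that segment does to contacts across the deletion. The upstream flank met the 500 kb beyond the segment 2.59 times as often in DelB as in DelBs (2.56 to 2.61, from 113007 and 45636 counts). After the expected level at each allele's own distance was taken into account, DelB remained higher at 1.60 against 1.01 in DelBs, a ratio of 1.58 (1.56 to 1.60). In DelBs the upstream flank reached the segment itself at 1.29 times the expected level (1.28 to 1.30), and the first 200 kb beyond the segment at 0.829 times (0.818 to 0.841). The first 200 kb beyond the deletion stood at 1.56 times the expected level in DelB. WT showed a step at the same place, with 3.35 times the expected level at the segment and 1.85 times beyond it, as did InvF with 3.56 and 1.90 times.

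Over 439 placements of untouched blocks 200 kb apart the DelB to DelBs ratio of observed over expected lay between 0.89 and 1.14. Of these, 0 reached 1.58. The expected level is each library's own decay over such same-side pairs, so their ratio lies near 1 whatever the decays are. The range therefore gives local variation about that level and does not test the decay. The flanks adjoin on the DelB allele, so the placements match the separation in DelBs alone. Contacts of the segment with the 500 kb downstream of it were close to WT in DelBs, at 1.04 times (1.03 to 1.06).

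The insulation score, which is low where few contacts cross a position, located boundaries between domains. WT had 22 boundaries. Of those outside the deletion, DelB kept a boundary within 50 kb at 16 of 20 and DelBs at 18 of 21, and InvF did so at 17 of 22. The WT boundaries after 73330000, 75100000 and 79140000 were matched in none of the mutants. Their WT depths were 0.22, 0.24 and 0.24 against the required 0.2. DelB and InvF also missed the boundary after 75310000, with a boundary after 75250000 instead. InvF also missed the boundary after 75930000, which had a WT depth of 0.23. These counts therefore do not by themselves show lost boundaries. The boundary after 77940000, inside the segment that only DelB lacks, had a score of -0.76 in WT, -0.76 in InvF and -0.58 in DelBs. The DelBs difference to WT of 0.18 has no settled direction, as it was -0.034 with balanced values, although balancing also raised the deleted bins. In reference order it was -0.24, but the 200 kb window then takes in deleted bins, which lowers the score by construction. At the DelB junction the score was 0.06. DelB had a boundary after 78180000 with a score of -0.34, at a position where WT had 0.36, DelBs 0.35 and InvF 0.40. The difference of DelB to WT, -0.69, lay between -0.82 and -0.38 under the alternatives. The 200 kb window there reaches past the junction, so it takes in other sequence in DelB than in WT. The alternative in reference order takes in deleted bins, which lowers the score by construction. DelBs had a boundary 30 kb from 78180000, after 78210000, with a score of 0.21 and a depth of 0.21 against the required 0.2. In InvF the boundary after 77510000 was at -0.73 against -0.72 in WT.

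Across 15 WT boundaries outside and over 200 kb from every rearranged interval, the differences to WT had an SD of 0.04 in DelB, 0.12 in DelBs and 0.08 in InvF. The number of WT boundaries depended on the definition: a 100 kb window gave 29, a 400 kb window 14, and a required depth of 0.4 gave 12.

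**Figure D2:**
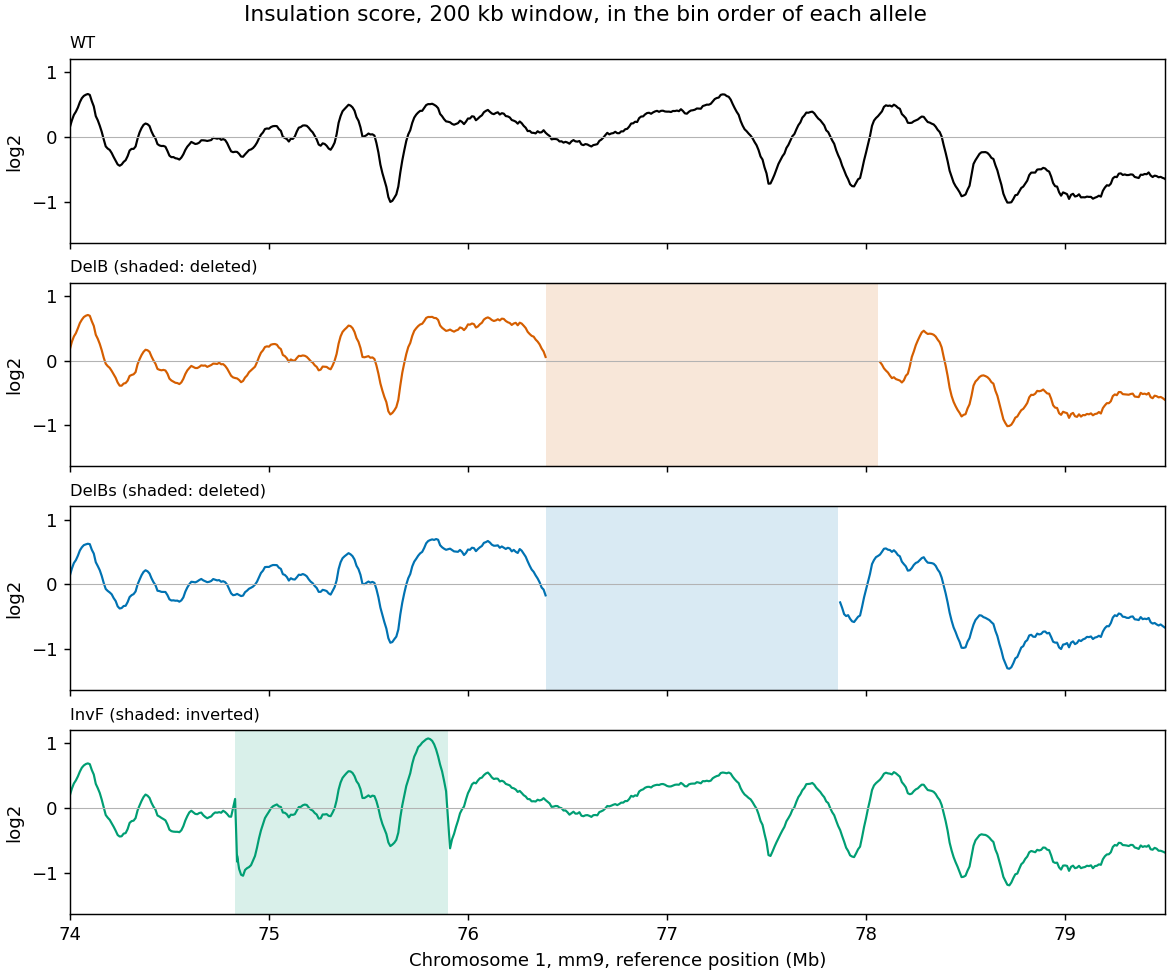
Insulation score on the log2 scale against the reference position in Mb, with 1 panel per library, computed in the bin order of each allele and drawn at reference positions. Shading marks the interval deleted or inverted in that library. The dip after 77940000 is at -0.76 in WT and InvF and at -0.58 in DelBs, a difference that turned with balanced values. This dip lies in the deleted part of DelB.

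The inversion exchanges the sequence that borders the Epha4 side of the map. In InvF the 250 kb blocks brought together at the left junction met 24.2 times as often as in WT (22.9 to 25.7, from 36645 and 1217 counts), and those at the right junction 8.91 times (8.47 to 9.39, from 17704 and 1597 counts). Contacts across the left breakpoint were at 0.153 of WT (0.147 to 0.158) and across the right breakpoint at 0.0648 (0.0622 to 0.0675). The first 250 kb of the inverted interval, from 74830001 to 75080000, had 6.25 times its WT contacts with the interval deleted in DelB (6.11 to 6.39), while the last 250 kb, from 75650001 to 75900000, kept 0.0993 of them (0.0972 to 0.101). The block from 74800001 to 74900000 met the block from 77500001 to 77600000 15.6 times as often as in WT (13.2 to 18.4), the only one of the 10 highest blocks of InvF that lay away from the junctions.

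At the same junction blocks the ratios to WT were 1.04 on the left and 1.19 on the right in DelB, and 1.11 and 1.34 in DelBs. Untouched blocks gave InvF to WT ratios of 0.91 to 1.15 over 415 placements at the junction separation and of 0.87 to 1.08 over 579 placements of adjoining blocks. The ratios at the junctions and across the left breakpoint followed the block size: with 100 kb blocks they were 38.3, 26.0 and 0.0987 and with 500 kb blocks 8.03, 4.62 and 0.328, while the right breakpoint, at 0.0721 and 0.102, had its lowest value with 250 kb blocks.

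The new neighbours met at different levels for their distance. At the left junction observed over expected was 1.28 (1.27 to 1.29), and at the right junction 0.619 (0.610 to 0.628). The WT boundary after 74870000 lies 40 kb from the right junction on the inverted allele. Its score was -1.05 in InvF against -0.30 in WT, a difference of -0.74 that lay between -1.60 and -0.57 under the alternatives. The 200 kb window there reaches past the junction, so it takes in other sequence in InvF than in WT. In InvF the score was also low at the right junction itself, at -0.74, against 0.14 at the left junction. The 250 kb to the right of the inversion met the 40 kb before that boundary at 0.886 times the expected level (0.866 to 0.906) and the 40 kb beyond it at 0.659 times (0.638 to 0.681), or at 0.609 and 0.503 times with balanced values. The boundary after 75610000 was shallower in InvF, at -0.59 against -1.003 in WT, while it stood at -0.83 in DelB and -0.90 in DelBs. Its difference to WT was 0.41 in InvF (0.39 to 0.69 under the alternatives), 0.17 in DelB (0.091 to 0.47) and 0.10 in DelBs (0.027 to 0.36).

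**Figure D3:**
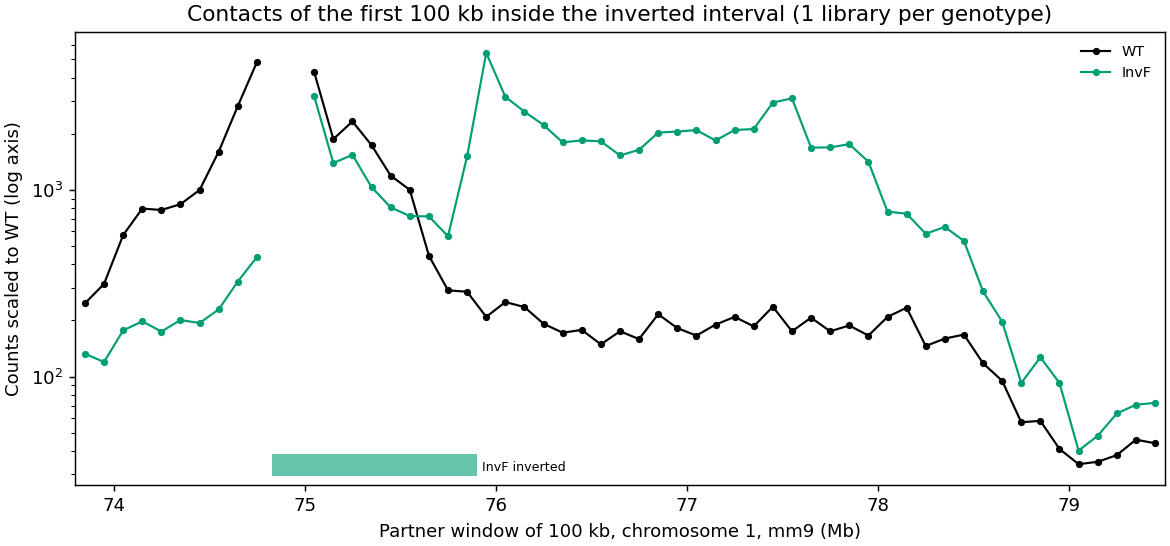
Contacts of the first 100 kb inside the inverted interval with windows of 100 kb in WT and InvF, as counts scaled to WT on a log axis against the reference position in Mb, with no error bars and a gap at the windows that overlap the viewpoint. The ratio of InvF to WT was 26.0 at 75900001 to 76000000, 17.7 at 77500001 to 77600000 and 3.66 at 78000001 to 78100000.

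Over the whole map, blocks of 100 kb by 100 kb were compared with WT. In DelB 226 of 3197 blocks were over 1 log2 unit higher and 0 were lower by as much, and 225 of the 226 paired the opposite sides of the deletion. In DelBs 158 of 3313 blocks were higher, all of them across the deletion, and 2 were lower. In InvF 127 of 4372 blocks were higher and 216 lower, and 127 and 203 of these touched the inverted interval. Of the 10 highest blocks of DelB, 5 paired 75800001 to 76300000 with 78100001 to 78200000 and together stood at 10.6 times WT (10.1 to 11.04). Of the 10 highest blocks of InvF, 9 lay where 74500001 to 74900000 meets 75600001 to 76000000, and these 9, which are part of that area, together stood at 19.6 times WT (18.8 to 20.6). Of the 10 lowest blocks of InvF, 6 lay where 75600001 to 75800000 meets 75900001 to 76400000, and these 6, again part of the area, together stood at 0.0564 of WT (0.0535 to 0.0595). The group of blocks that held the highest value in DelBs, 76200001 to 76300000 with 78300001 to 78500000, stood at 3.86 times WT (3.55 to 4.19).

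Among blocks on 1 side of every rearrangement, 0 of 1184 in DelB, 0 of 1183 in DelBs and 1 of 1180 in InvF passed the same limit. The numbers depend on the block size, with 727 higher blocks of 50 kb and 48 of 200 kb in DelB, and 504 higher and 590 lower blocks of 50 kb and 38 and 39 of 200 kb in InvF. They also depend on the scaling: with each distance matched and the last expected value held beyond its range, 1320 blocks were higher in DelB and 281 in DelBs, and 1361 were higher and 159 lower in InvF, while without the blocks beyond that range 157, 148 and 137 were higher and 159 lower in InvF. In these untouched parts the 6 pairs of libraries had correlations of log2 observed over expected between 0.969 and 0.980 over 3756 blocks of 50 kb, which are not independent replicates. Counts fell with distance at slopes from -0.903 to -0.865 on log10 scales.

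**Figure D4:**
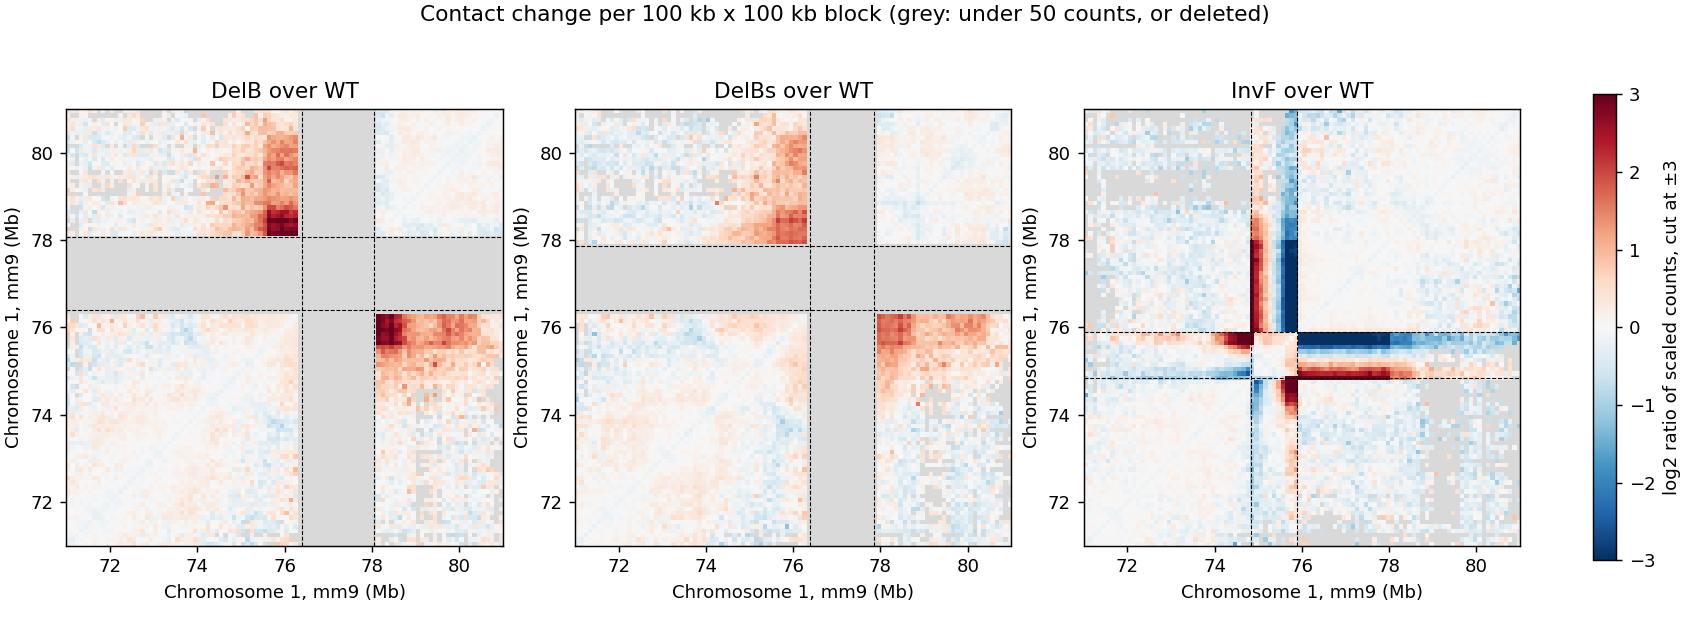
Log2 ratio of scaled counts to WT per 100 kb by 100 kb block, with 1 panel per mutant and both axes giving the position in Mb; colours are limited at 3 units either way, dashed lines mark the ends of the rearranged interval, and grey marks deleted bins and blocks under 50 counts. Of the blocks over 1 unit higher, 225 of 226 in DelB and 158 of 158 in DelBs pair the opposite sides of the deletion.

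The difference maps deposited by the authors cover 73000001 to 79000000 and have a positive value where the mutant is higher. In the authors' deposited table for DelB, 2579 of 2583 values above 0 pair opposite sides of the deletion, and in that for DelBs 2528 of 2543 do, outside the first row and last column of those tables. In the authors' deposited table for InvF, 2914 of 3482 values above 0 and 3905 of 3994 below 0 have a bin in the inverted interval.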

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

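Counts inside the deleted intervals stood out because no contact should come from sequence that a homozygous deletion removes. They reached 2.23% of the WT level in DelB (2.204% to 2.26%, 25157 counts) and 1.14% in DelBs (1.12% to 1.16%, 11726 counts). Every deleted bin with enough WT counts to be judged held some, from 1.57% to 2.87% of WT in DelB and from 0.875% to 1.55% in DelBs. The tests below were written before their results were seen; the distance-matched version of the carry-over test was added after.

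Random ligation or wrongly placed reads should weigh most at long distance. The residual share at 500 kb to 1.5 Mb was 1.17 times that at 20 to 100 kb in DelBs and 1.09 times in DelB. Both were below the limit of 1.5 set for them, which argues against random ligation or wrongly placed reads as the main source. The share did rise with distance, from 2.00% at 0 to 10 kb to 2.47% at 500 kb to 1.5 Mb in DelB. In DelBs it rose from 0.967% to 1.33%, so a smaller part from wrongly placed reads stays open. Random ligation joins only DNA that is present, so it needs chromosomes without the deletion to give counts inside the interval. Chromosomes without the deletion, from cells, DNA or reads of another genotype, remain a candidate explanation: the share of pairs with both bins inside was 0.830 of the share with 1 bin inside in DelBs and 0.906 in DelB, within the range set for them beforehand. Whether InvF reads were the source could not be settled. At the InvF junctions the excess was 0.781 of the predicted one in DelBs (0.289 to 1.27) and 0.134 in DelB (-0.110 to 0.375), and with each distance matched 0.562 and 0.0181. DelB alone lies below the limit of 0.5. In DelBs the right 100 kb corner stood at 1.52 times WT (1.29 to 1.80) and the left at 1.08 times (0.920 to 1.28). InvF itself held more counts at the left, 11322 against 6748, so carry-over should add more there. With 250 kb blocks the right junction was above WT in DelB as well, at 1.19 times, and at 1.34 times in DelBs. The question stays open, and no biological explanation was tested.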

How the results depend on the processing

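No paired analysis was possible because each genotype has 1 library. Directions held under every alternative run for the contact ratios across the deletions, between DelB and DelBs and at the InvF junctions and breakpoints. Observed over expected was 1.09 for a simulated deletion with no excess, with 500 kb flanks at another position. In DelB it stayed above 1 under the alternatives run, but fell to 1.11 with 250 kb flanks. Between the 100 kb flanks it was 1.02 (0.999 to 1.04). In DelBs it turned to 0.823 with balanced values and to 0.935 with 250 kb flanks, and the cause was not tested. Balancing also raised the deleted bins to the sum of other bins, so balanced values near the deletions are not a clean check. Observed over expected is left as it is by a single scaling factor and already matches distance, so those settings give no further value. The inverted interval stayed the same under 3 alternatives, and the share limits of 5% and 25% moved the deletions by at most 10 kb. With balanced values both deletions measured 0 kb by either rule: no bin inside them lacked a value, and no run of bins fell under the 10% share. The limits of the data are 1 library per genotype and counting intervals that ignore duplicates.

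With balanced values the DelB and DelBs to WT ratios were 7.96 and 3.51, observed over expected in DelB 1.198, the DelB to DelBs ratios 2.43 for counts and 1.497 for observed over expected, the right junction of InvF 8.22 and the breakpoints 0.132 and 0.0706. Scaling by all counts gave 11.49 and 4.89 across the deletions, 9.41 at the right junction, and 0.161 and 0.0684 at the breakpoints. Matching each distance gave 8.26 and 3.40 across the deletions and 2.65 for DelB to DelBs. Between the 100 kb flanks of the deletions the ratios to WT were 19.4 in DelB and 6.89 in DelBs. Flanks of 250 kb gave 10.9 and 4.48 across the deletions, and 3.38 and 1.69 for DelB to DelBs. Flanks of 1000 kb gave 6.33 and 3.21, 1.32 for observed over expected in DelBs, and 2.17 and 1.52. For InvF, 100 kb flanks gave 38.3 and 26.0 at the junctions and 0.0987 and 0.0721 at the breakpoints, and 500 kb flanks 8.03, 4.62, 0.328 and 0.102. Without poorly covered bins observed over expected was 1.57 in DelB and 1.08 in DelBs. Without breakpoint bins the ratios were 8.17 and 3.48 across the deletions, 1.64 and 1.099 for observed over expected, 2.47 and 1.60 for DelB to DelBs, 19.6 and 6.64 at the junctions, and 0.165 and 0.0525 at the breakpoints.

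A 100 kb window gave 29 boundaries in WT with 27 found in InvF, and a 400 kb window gave 14 boundaries in WT with 11 found in DelBs. A required depth of 0.4 gave 12 in WT, with 10 found in DelB and 11 in DelBs. Blocks of 50 kb gave 727 higher and 2 lower in DelB, 617 higher in DelBs, and 504 higher and 590 lower in InvF, while blocks of 200 kb gave 48 higher in DelB, 27 higher and 0 lower in DelBs, and 38 higher and 39 lower in InvF; smaller blocks are more numerous by construction. Lower blocks numbered 1 in DelB and 5 in DelBs with a minimum count of 20, and in DelBs 0 with 200, 5 with balanced values, and 7 after thinning. Matching each distance with the last expected value held beyond its range, as first written, gave 1320 higher blocks in DelB, 281 higher and 1 lower in DelBs, and 1361 higher in InvF. Leaving out the blocks beyond that range, chosen after seeing the data, gave 157, 148 and 137 higher and 1 lower in DelBs. Correlations between libraries spanned 0.984 to 0.992 with 100 kb blocks and 0.961 to 0.975 with balanced values. From 100 kb to 2 Mb the slopes were -1.06 in WT, -1.02 in DelB, -1.02 in DelBs and -1.06 in InvF. Of 350 values of single regions under the alternatives, 330 stayed on their side of 1. Of 72 differences in insulation at single boundaries, 47 stayed within 1 SD and 0 called ones turned sign. The DelBs difference after 77940000, 0.18 and not called, turned to -0.034 with balanced values, where the deleted bins were also raised, and the cause was not tested. In reference order it was -0.24, where the window takes in deleted bins, so that value does not bear on its direction.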

Other observations

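Outside the comparisons, the upstream flank of the deletions met more than its near downstream partners. Its contacts with the window from 79100001 to 79200000, over 1 Mb beyond the deletions, were 1.94 times WT in DelB and 1.82 times in DelBs, against 0.802 in InvF. Both deletions shorten the distance to this window, which raises contacts by itself, and these ratios were not set against the expected level. Contacts of the downstream 500 kb of DelB with the next 500 kb were 0.956 of WT in DelB, 0.857 in DelBs and 0.901 in InvF. In InvF the last 100 kb of the inverted interval met 74700001 to 74800000 at 25.3 times WT and 74000001 to 74100000 at 2.64 times.

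KR balancing changed the deletion maps in a way a reader of the balanced files would want to know. The median sum per deleted bin was 100% of that of other bins in both deletion libraries, against 3.19% in DelB and 1.71% in DelBs in the raw maps. The interval held 870329 units in the balanced DelB map and 25157 counts in the raw one, and 808374 against 11726 in DelBs. In the authors' deposited tables of differences the last column held 72 to 74 values that were not 0, reaching 215.8 in DelB, and none of them lay within 5% of the recovered formula.

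Relative to the expected level at each allele's own distance, contacts across the deletion were fewer in DelBs than in DelB. The 3 tests of this were written before their results were seen. Uneven capture of bins was tested with the balanced values. There the DelB to DelBs ratio of observed over expected was still 1.497, above the limit set beforehand. Balancing also raised the deleted bins, which differ between DelB and DelBs, so this value does not settle the question. A different decay with distance could not be tested by the untouched blocks, of which 0 of 439 overlapping placements reached the observed ratio. The expected level is each library's own decay over such same-side pairs, so their ratio lies near 1 whatever the decays are. Separation of the flanks by the 200 kb segment that only DelB lacks is a hypothesis consistent with the step in DelBs, where observed over expected was 1.55 times as high at the segment as in the first 200 kb beyond it; WT and InvF showed the step as well, at 1.81 and 1.88. With 1 library per genotype a difference between the embryos or libraries stays open and was not tested.

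In both deletion libraries the upstream flank also met sequence upstream of it more often, where nothing is rearranged: with the 500 kb left of the inverted interval the ratio to WT was 1.30 in DelB (1.24 to 1.36) and 1.42 in DelBs (1.36 to 1.49), against 1.03 in InvF (0.976 to 1.08). With the inverted interval, which lies nearer, it was 1.21 and 1.27, and farther left it was 1.08 (1.03 to 1.13) and 1.04 (0.995 to 1.097) at 500 kb to 1 Mb, 0.960 and 0.953 at 1 to 2 Mb and 1.17 and 1.15 at 2 to 3 Mb. All 3 tests of this pattern were written after related values had been seen, and none decided. Counts freed from deleted partners could raise the others, but the flank's scaled sum was 80.1% of WT in DelBs and 84.1% in DelB, between the limits of 80% and 90%. A changed decay with distance and better recovery of the flank bins cannot be told apart from it either: with each distance matched the ratio was still 1.19 in DelB and 1.28 in DelBs against a limit of 1.2, and the ratio exceeded that within the flank by 1.13 times and 1.2499 times against the same limit.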
